A study of Lysinibacillus sp. B2A1 with 4 samples.

How the data were processed

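The data are the authors' deposited tables for 4 RNA-seq libraries of Lysinibacillus sp. B2A1, 2 from cells kept without arsenic mineral and 2 from cells kept with arsenopyrite for 12 h in artificial groundwater. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a strand-specific kit of Agilent. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.32, HISAT2 2.1.0, SAMtools 1.2, Cufflinks 2.2.1 and Cuffdiff were used; which step each served, the strand setting of the counting, the genome build and the annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart.

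Per the file headers, the authors' values per library are FPKM, and the authors' table also gives a log2 ratio of the group means, a p-value and a q-value for each gene. The scaling between libraries is not given in the sources used here. The lowest value in the table was 1e-05 FPKM, which stands for no estimated expression and was taken as 0; it was held by 315 and 308 genes in control 1 and 2 and by 218 and 228 in arsenopyrite 1 and 2. At this floor were 43 genes in both controls only, 3 in both arsenopyrite libraries only and 182 in all 4. Such a value can be a failed estimate: the gene ffs of the signal recognition particle RNA was listed at 0 in both controls and at 408544 and 233657 FPKM in arsenopyrite 1 and 2, and rnpB and ssrA were listed at 0 throughout. Median FPKM over all genes was 32.1, 32.5, 35.0 and 41.1 in control 1, control 2, arsenopyrite 1 and arsenopyrite 2. FPKM of ribosomal RNA genes summed to 16427, 18079, 26138 and 29011.

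Whether the values held whole reads was checked on 2767 loci of a single protein-coding gene of 450 to 3000 bp, by fitting the worth of 1 read and a length offset per library. Low values came out whole within 0.1 of a read for 100% of 177 values in control 2 and 100% of 55 in arsenopyrite 2, against 36.3% of 102 in control 1 and 42.6% of 54 in arsenopyrite 1, where the same fit was tried; 20% would fall that near by chance at a fixed scale. Depth was therefore recovered for replicate 2 only, and how the replicate 1 values were made is not given in the sources used here. Values within each replicate number are given beside the pooled counts, the medians of the lists that passed camera, the regions, and the log2 fold changes of genes. Since FPKM are not counts, no count model was used.

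Gene names, products and positions were taken from the authors' table, with positions counted from 1. Many of its loci span several neighbouring genes, so positions are printed only where a locus held 1 gene. Genes with a mean of at least 1 FPKM over the 4 libraries (5143) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale and understate the change of low genes. Gene lists, 23 in number, were fixed before the data were examined as patterns on symbols and products, and were tested with camera of limma at a preset correlation of 0.01 and, as an alternative, an estimated correlation, with adjustment over the lists. Some genes sit in several lists. With an estimated correlation 0 of the 8 lists that passed kept an adjusted p under 0.05.

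The genes named in the text follow a rule written before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold with groups that do not overlap, at least 10 FPKM in the higher group and a product that is not hypothetical, uncharacterized or of unknown function (genes with no product or only a domain of unknown function were left out with these); every member of the arsenic resistance list; and the 3 members with the smallest p of each other list that passed camera. Other genes are named where a count of 5 or fewer, or a feature singled out, needed it; those were chosen after their values were seen. These include the fallen or risen exceptions of each list, the catalase, hydroperoxide resistance, msrB, rplU, rpmG and rhodanese genes in the results, and all genes of the closing section that the rule does not give.

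The test was checked on simulated data for the 5143 genes. At a log2 fold change of 1 it recovered 0 of 66 genes, at 2 27 of 67 (40.3%) and at 3 55 of 67 (82.1%), with 8 of 90 calls false. In the simulation, genes that changed by 2-fold were thus out of reach. It held few changed genes, none of them low, and gave 90 calls against 1081 in the data. Benjamini-Hochberg adjustment is stricter where fewer genes change, and the simulated groups had equal spread, so these shares do not carry over to the data.

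Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter or a minimum of 10 FPKM, median-of-ratios scaling (factors of 0.976, 1.01, 0.983 and 1.02), quantile normalization, leaving out each library, the replicate number as a block, eBayes without trend or with robust estimation, ribosomal and transfer RNA left out, and a 2-fold minimum. Loci of 1 gene only, the same with at least 450 bp, and genes above the floor in every library were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and plots.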

Results

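Lysinibacillus sp. B2A1 is a bacterium of the order Bacillales. Log-phase cells of this strain were washed and kept for 12 h in artificial groundwater, either with arsenopyrite, an iron arsenic sulfide mineral, or without any arsenic mineral. RNA was sequenced from 4 strand-specific libraries, 2 control and 2 arsenopyrite, which the labels call biological duplicates. The comparison asks which transcripts differ when the cells meet the mineral. The authors' FPKM values, which scale fragments to transcript length and library size, covered 5417 genes, of which 5057 were protein coding. The FPKM values summed to 5.40e+06 in control 1, 5.58e+06 in control 2, 4.78e+06 in arsenopyrite 1 and 3.15e+06 in arsenopyrite 2. The 10 genes of highest FPKM held 58.4%, 58.9%, 59.6% and 47.3% of these sums. Depth could be read from the values of replicate 2 only: on 2767 loci of a single protein-coding gene, the values came to 4101661 reads in control 2 and 5498453 in arsenopyrite 2. In those libraries 1 read on a locus of 1000 bp was worth 0.158 and 0.0911 FPKM.

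Exposure to arsenopyrite went with a large change of the transcriptome. Among the lists fixed beforehand, 7 of 9 arsenic resistance genes, 7 of 18 phosphate uptake genes, 9 of 32 genes for other metals and 30 of 91 sporulation genes rose, and 18 of 31 genes of fatty acid degradation fell. Of 5143 genes tested with limma on log2(FPKM + 1), 1081 passed an adjusted p of 0.05, 533 higher and 548 lower with arsenopyrite. All 1081 differed by at least 2-fold on that scale and had the same direction in both replicate numbers. Passing the test with 2 libraries against 2 largely entails both. A difference of at least 2-fold with both arsenopyrite libraries on one side of both controls was seen in 1749 genes, 993 higher and 756 lower. Chance alone separates 2 libraries from 2 others in 33.3% of genes, and 3447 genes were separated in all. Under quantile normalization the split of such genes became 738 higher and 909 lower. Without control 1 or control 2 the limma count was 474 or 427, and without arsenopyrite 1 it was 1940; with no filter on low values it was 479.

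The replicates of the controls were closer to each other than those of the exposed cells. Across genes, Pearson's r of the log2 values was 0.982 between the controls, 0.945 between the arsenopyrite libraries and 0.839 to 0.878 between the groups; genes are not independent replicates. The median absolute log2 difference was 0.22 between the controls and 0.59 between the arsenopyrite libraries. Replicates 1 and 2 differed in 1 further respect: in the fits made here, low values came out as whole numbers of reads, within 0.1, for 100% of those tested in control 2 and arsenopyrite 2, but for 36.3% in control 1 and 42.6% in arsenopyrite 1. How the values of replicate 1 were made is not given in the sources used here. Within replicate 1, 1746 genes differed by at least 2-fold, and within replicate 2, 2049 did. Of these, 1201 did so in both with the same direction, 651 higher and 550 lower, and 13 with opposite directions. In the following, a pair of values in brackets after a gene's log2 fold change gives it within replicate 1 and within replicate 2.

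The arsenic resistance genes showed the strongest response of any list fixed before the data were examined. Of 9 tested members, 7 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 6.14. It was 6.46 within replicate 1 and 5.73 within replicate 2. In the operon, arsA, the ATPase that drives the arsenite pump, went from 4.37 ± 0.642 to 521 ± 109 FPKM (SD, n = 2), a log2 fold change of 6.59 ± 0.33 SE (6.93, 6.26). The arsenate reductase gene arsC, which turns arsenate into arsenite, lies at positions 3213209 to 3213628 of the chromosome record in the authors' table and went from 11.9 ± 2.03 to 936 ± 255 FPKM (SD, n = 2). The gene for the metallochaperone and repressor ArsD, C3943_15300, rose by 6.14 (6.49, 5.78) on the log2 scale, and arsB C3943_15290, which encodes the membrane pump, by 6.18 (6.46, 5.90). In the authors' deposited table arsB C3943_15290 shares its locus with C3943_15285, and arsA with C3943_15310. The arsenite methyltransferase gene arsM C3943_15315 reached 1111 ± 374 FPKM from 7.29 ± 0.54 (SD, n = 2; log2 fold change 7.03, limma adjusted p = 0.000469), with 7.31 within replicate 1 and 6.74 within replicate 2. At a separate locus, arsM C3943_16600 rose by 5.15 (5.84, 4.45) and the pseudogene arsB C3943_16605 by 5.64 (6.40, 4.88) on the log2 scale. The remaining members did not pass the test: C3943_16485, a predicted arsenic resistance protein, stood at 43.6 ± 11.8 FPKM in controls and 64.2 ± 14.7 with arsenopyrite (SD, n = 2; limma adjusted p = 0.311), and the efflux pump gene C3943_24755 at 1.40 ± 1.16 and 2.40 ± 0.66 FPKM (SD, n = 2; limma adjusted p = 0.429). As a set the list passed limma's camera (adjusted p = 2.9e-07), with an adjusted p = 0.80 with an estimated correlation.

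**Figure D1:**
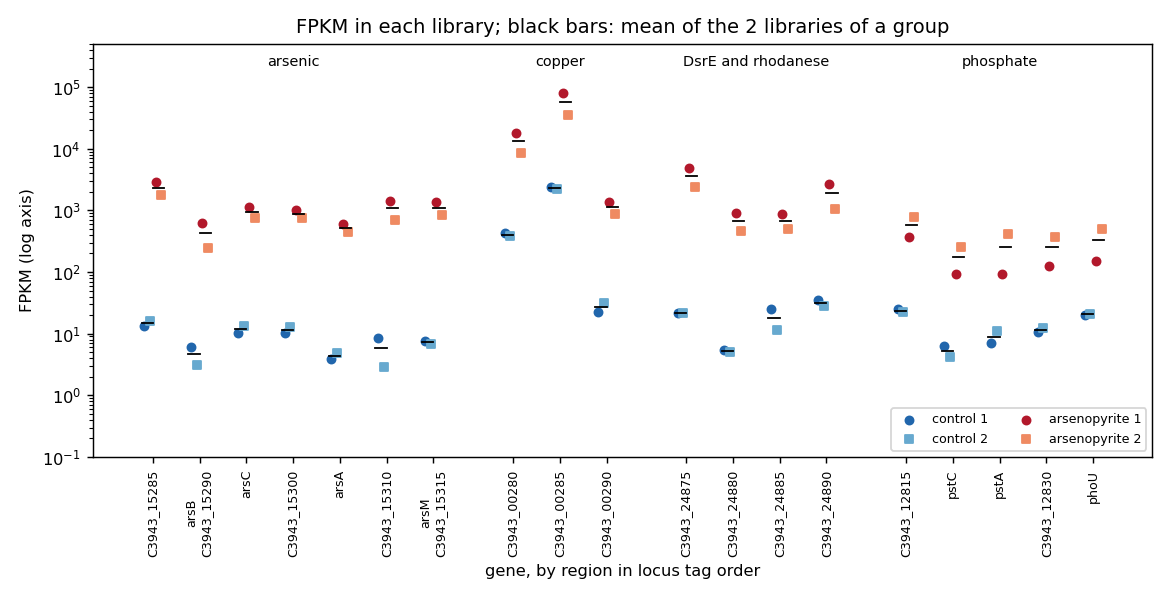
FPKM on a log axis of genes of the arsenic, copper, DsrE and rhodanese, and phosphate regions in each of the 4 libraries, in locus tag order; black bars are the means of the 2 libraries of a group. The DsrE and rhodanese region was chosen after its values were seen. Both arsenopyrite libraries lie above both controls for every gene shown; arsenopyrite 1 is the higher of the exposed libraries in the first 3 regions and arsenopyrite 2 in the phosphate region.

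In the list of other metal transport and resistance genes, 9 of 32 tested members rose, 1 fell and 22 did not pass the test (10 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.72, 0.44 within replicate 1 and 0.95 within replicate 2. The copper chaperone gene copZ, C3943_00285, stood at 2317 ± 130 FPKM in controls and reached 57363 ± 31659 FPKM (SD, n = 2). Its locus is about as short as the length offsets of 202 and 204 bp fitted in control 2 and arsenopyrite 2, so these levels are uncertain. Its neighbour C3943_00290, a copper-exporting P-type ATPase at positions 53701 to 56112, rose from 27.3 ± 6.30 to 1135 ± 357 FPKM (SD, n = 2; log2 fold change 5.31 ± 0.35 SE, limma adjusted p = 0.000791), with 5.87 within replicate 1 and 4.76 within replicate 2. A further heavy-metal P-type ATPase gene, C3943_23290, rose by 4.50 (4.89, 4.10) on the log2 scale. The member that fell was C3943_23190, annotated as an ATPase of dipeptide, oligopeptide or nickel uptake, with a log2 fold change of -2.57 (-2.42, -2.72). The list passed camera at an adjusted p = 0.0097, and gave an adjusted p = 0.80 with an estimated correlation. Without arsenopyrite 2 its adjusted p was 0.053, the highest of its alternatives, which began at 0.00498, and its median ran from 0.29 to 1.05 over them.

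Of 18 tested members of the phosphate uptake list, 7 rose, none fell and 11 did not pass the test (9 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 1.22, 0.91 within replicate 1 and 1.61 within replicate 2. The phosphate-binding protein gene C3943_12815 went from 23.7 ± 1.67 to 579 ± 304 FPKM (SD, n = 2). Its neighbour pstC, a permease subunit of the high-affinity phosphate transporter, rose by 4.64 ± 0.53 SE (3.69, 5.59) on the log2 scale, and the transporter's ATP-binding subunit C3943_12830 by 4.15 (3.45, 4.84). With their neighbours pstA and phoU these made 5 of the 7; the others were the alkaline phosphatase gene C3943_09375 and the phosphonate transport gene C3943_08000. With no filter on low values C3943_12830 had a limma adjusted p of 0.0518. The list passed camera (adjusted p = 0.0015; adjusted p = 0.80 with an estimated correlation). Its median ran from 0.753 under quantile normalization to 3.29 on loci of a single gene of at least 450 bp.

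In the list of sporulation and germination, 30 of 91 tested members rose, 2 fell and 59 did not pass the test (43 higher and 2 lower adjusted over the list alone). The median log2 fold change was 1.17, 0.78 within replicate 1 and 1.64 within replicate 2. The spore coat protein gene C3943_21360 rose from 4.98 ± 1.36 to 925 ± 638 FPKM (SD, n = 2; log2 fold change 7.10 ± 0.54 SE, limma adjusted p = 0.00127), with 6.10 within replicate 1 and 8.10 within replicate 2. The outer coat gene cotZ, C3943_04530, went from 15.7 ± 0.736 to 1048 ± 855 FPKM (SD, n = 2), and C3943_15065, a small protein of the YjcZ family, rose by 4.43 (3.78, 5.07) on the log2 scale. YjcZ genes occur in several copies here, and reads shared between copies leave their levels uncertain. The members that fell were C3943_27030, annotated as the sporulation initiation inhibitor Soj, and the germination gene C3943_14785, with log2 fold changes of -1.58 (-1.23, -1.93) and -1.34 (-1.50, -1.18). The list passed camera (adjusted p = 2.9e-07; adjusted p = 0.80 with an estimated correlation).

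In the list of transposases, integrases and prophage genes, 21 of 72 tested members rose, 3 fell and 48 did not pass the test (22 higher and 3 lower adjusted over the list alone). The median log2 fold change was 0.86, 0.45 within replicate 1 and 1.08 within replicate 2. The list had 136 members, and only the 72 passed the filter on low values. A member listed at 0 in both controls could enter only by rising, so the filter favours rises. The 3 that fell were the transposase C3943_09405 and the integrases C3943_21785 and C3943_16795. The phage holin gene C3943_06920, whose product opens the cell membrane, rose from 6.02 ± 0.10 to 323 ± 214 FPKM (SD, n = 2). The terminase gene C3943_02280 was listed at 0 in both controls and at 10.9 and 12.4 FPKM in arsenopyrite 1 and 2, and the holin gene C3943_08070 was listed at 0 in both controls and at 29.2 and 102 FPKM, with a q-value of 0.249 in the authors' deposited table. A listing at 0 can be a failed estimate, since the gene of the ribonuclease P RNA, which matures transfer RNA, was listed at 0 in all 4 libraries. Without the 4 members listed at 0 in a whole group the median was 0.68. The list passed camera (adjusted p = 0.00051; adjusted p = 0.80 with an estimated correlation), and did so in 13 of 17 alternatives. It did not with no filter on low values (median 0, adjusted p = 0.0822), on genes with a mean of at least 10 FPKM (0.0607), on loci of a single gene (0.256) or on such loci of at least 450 bp (0.427, the highest of a range that began at 3.68e-05). Over all tested genes, the median log2 fold change went with the level: it was 0.54 over the 503 genes with a mean of 1 to 5 FPKM and -0.35 over the 1707 genes with a mean of at least 100 FPKM.

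**Figure D2:**
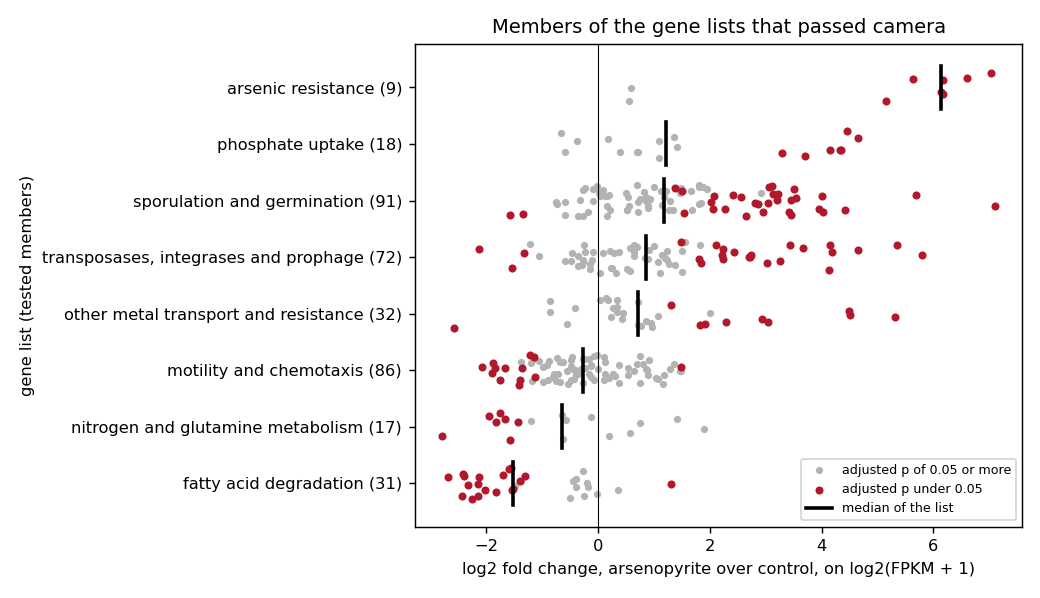
Log2 fold change of every tested member of the 8 lists that passed camera, 1 point per gene, with the median of each list as a black bar; red points passed an adjusted p of 0.05, and members listed at 0 in the controls are drawn at their fitted value. The medians run from 6.14 for arsenic resistance to -1.52 for fatty acid degradation.

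Of 31 tested members of the fatty acid degradation list, 18 fell, 1 rose and 12 did not pass the test (20 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.52, -1.40 within replicate 1 and -1.45 within replicate 2. The electron transfer flavoprotein subunit gene C3943_10615, whose product takes electrons from acyl-CoA dehydrogenases, fell from 3094 ± 109 to 645 ± 16 FPKM (SD, n = 2; log2 fold change -2.26 ± 0.27 SE, limma adjusted p = 0.00441), with -2.32 within replicate 1 and -2.20 within replicate 2. The long-chain fatty acid CoA ligase gene C3943_10600, at positions 2281503 to 2283194, and the enoyl-CoA hydratase gene C3943_10610 fell too, with log2 fold changes of -2.14 (-1.96, -2.31) and -2.02 (-2.11, -1.93). The member that rose was C3943_21520, annotated as a 3-hydroxyacyl-CoA dehydrogenase, by 1.30 (1.33, 1.27). The list passed camera (adjusted p = 2.9e-07; adjusted p = 0.80 with an estimated correlation). Without control 2, C3943_10600 and C3943_10610 had limma adjusted p of 0.0569 and 0.0936, the highest over their alternatives.

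In the list of nitrogen and glutamine metabolism, 7 of 17 tested members fell, none rose and 10 did not pass the test (8 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.64, -1.19 within replicate 1 and -0.50 within replicate 2. The glutamine synthetase gene glnA C3943_07290 fell from 4375 ± 799 to 651 ± 250 FPKM (SD, n = 2), and the glutamate dehydrogenase gene C3943_20940 fell with a log2 fold change of -1.66 (-1.62, -1.70). C3943_11320, with a log2 fold change of -1.95 (-1.71, -2.19), encodes a folylpolyglutamate synthase of folate metabolism and entered the list through its product's wording, as did its neighbour C3943_11325, at -1.43 (-1.19, -1.67). In the list of motility and chemotaxis, 12 of 86 tested members fell, 1 rose and 73 did not pass the test (8 lower and 0 higher adjusted over the list alone), with a median of -0.27, -0.30 within replicate 1 and -0.24 within replicate 2. The flagellar export chaperone gene flgN, C3943_04005, fell from 1090 ± 128 to 258 ± 29.3 FPKM (SD, n = 2), and so did the anti-sigma factor gene flgM and the motor gene motB, C3943_23315, with log2 fold changes of -1.90 (-1.72, -2.09) and -1.67 (-1.64, -1.71). The member that rose was the chemotaxis gene C3943_06250, by 1.48 (0.916, 2.04). The camera adjusted p was 0.0356 for the nitrogen list and 0.0492 for the motility list, with an adjusted p of 0.86 and 0.80 with an estimated correlation. Without arsenopyrite 1 these became 0.139 and 0.121, and without control 2 the motility list had 0.112. Under quantile normalization they were 0.053 and 0.096. Of 17 alternatives, the nitrogen list passed in 11 and the motility list in 8. The ranges over all alternatives were 0.0178 to 0.139 and 0.0308 to 0.154, and the medians ran from -1.43 to -0.598 and from -0.439 to -0.171. Against 10000 random lists matched on mean expression, a check added after the values were seen, the nitrogen median lay inside the range that leaves out the outer 0.05 of them (-0.665 to 0.564) and the motility median at the lower edge of its own (-0.272), while the medians of the other 6 lists that passed camera lay outside theirs. So did 4 lists that did not pass camera: iron and siderophore uptake (-0.126, below -0.0754), the respiratory chain (0.292, above 0.264), cell wall and surface layer (0.462, above 0.353) and ribosomal and transfer RNA (1.04, above 0.551). In limma, the call of C3943_20940, C3943_11320, flgM and C3943_23315 was lost without control 1 and also without control 2, with adjusted p of 0.0710 to 0.182 over these 4 genes, and that of C3943_04005 without control 2 (adjusted p = 0.0686).

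Ribosomal protein genes differed between the exposed libraries. Of 60 tested members 14 fell and 1 rose (15 and 1 adjusted over the list alone), and the list missed camera's threshold (adjusted p = 0.0600). The median log2 fold change was -0.15 in all, -0.81 within replicate 1 and 0.28 within replicate 2. Without arsenopyrite 2 the list was lower with an adjusted p = 1.24e-05, and without arsenopyrite 1 its median was 0.34 with an adjusted p = 0.609, which are the ends of the leave-out range. The gene rplU of L21 fell with a log2 fold change of -2.87 (-3.17, -2.57), while rpmG C3943_25000, a gene of L33, rose from 479 ± 72.6 to 9977 ± 2677 FPKM (SD, n = 2).

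**Figure D3:**
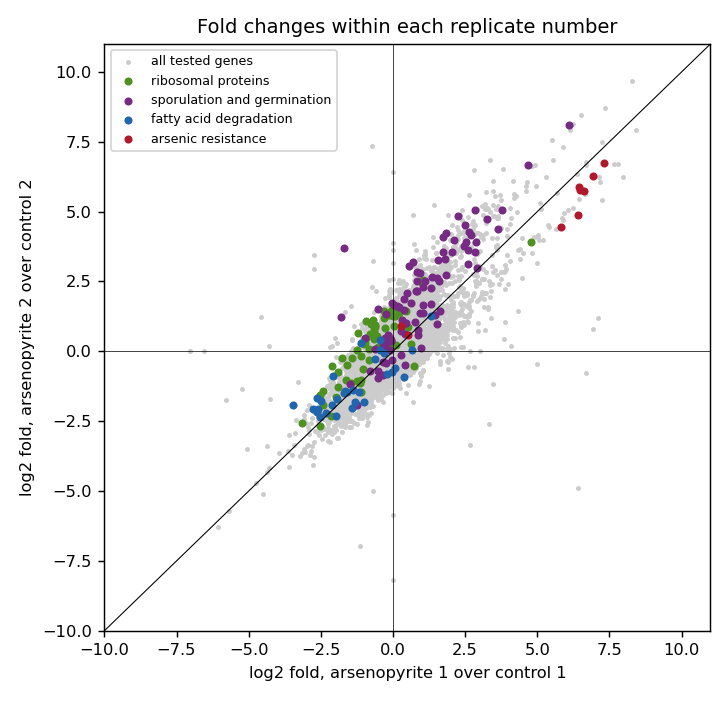
Log2 fold change within replicate 2 against that within replicate 1, 1 point per tested gene, with 4 lists in colour and the line of equal change; 1 gene lies outside the axes. Ribosomal protein and sporulation genes lie mostly above the line, with medians of -0.81 and 0.78 within replicate 1 against 0.28 and 1.64 within replicate 2, and arsenic resistance genes below it, at 6.46 against 5.73.

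The other 14 lists did not pass camera. Iron and siderophore uptake, with 2 of 36 members higher and 1 lower, had a median log2 fold change of -0.13 (adjusted p = 0.425), -0.36 within replicate 1 and 0.21 within replicate 2. Without arsenopyrite 2 it was lower at an adjusted p = 0.0221, and under quantile normalization at 0.0353, within a range of 0.0221 to 0.714. Oxidative stress defence had 7 higher and 3 lower of 33, arsC among the higher. The catalase gene C3943_01335 rose by 1.23 (1.35, 1.12) and the organic hydroperoxide resistance gene C3943_09165 by 3.05 (3.69, 2.41) on the log2 scale, while the methionine sulfoxide reductase gene msrB fell, at -1.23 (-0.999, -1.47). Sulfur and cysteine metabolism had 7 higher and 5 lower of 48, and among the higher were the rhodanese genes C3943_24885 and C3943_24890, at 5.20 (5.08, 5.31) and 5.69 (6.24, 5.15). Several members of this list are disulfide oxidoreductases, taken in by the wording of their product. Respiratory chain and ATP synthase had 5 higher and 1 lower of 47, and passed at an adjusted p = 0.00594 without arsenopyrite 1 and at 0.0270 under quantile normalization, within a range of 0.00594 to 0.951. The TCA cycle had 1 higher and 3 lower of 21 (median -0.58, adjusted p = 0.0850) and passed at 0.0271 without arsenopyrite 2 and at 0.0397 on loci of a single gene, within a range of 0.0136 to 0.3801. Fatty acid synthesis had 7 higher and 1 lower of 23, and cell wall and surface layer genes 7 and 2 of 54. Ribosomal and transfer RNA had 4 and 2 of 23, and passed at an adjusted p = 0.0287 without control 1, at 0.0273 under quantile normalization and at 0.0296 on loci of a single gene. The list had 120 members, so these 23 are the part that passed the filter on low values. Its range was 0.0273 to 0.618, with a median of 0 and the highest p with no filter on low values. Iron storage and iron-sulfur assembly had 2 higher of 14, 1 of them C3943_15310 of the arsenic operon. Heat shock chaperones and proteases had 2 lower of 15, the dnaK gene C3943_20625 and groL, DNA repair 1 higher and 1 lower of 38, glycolysis 1 lower of 12, the phosphofructokinase gene pfkA, and branched-chain and aromatic amino acid synthesis 1 higher and 1 lower of 39. Glycolysis passed without arsenopyrite 2 (adjusted p = 0.0308), and amino acid synthesis without arsenopyrite 1 (adjusted p = 0.0328), within ranges of 0.0308 to 0.967 and 0.0328 to 0.922. The 23 tested multidrug efflux genes did not pass the test.

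Among the annotated genes of any function that the naming rule gave, the largest rises included 3 genes annotated as uracil permease. The rule did not give ffs, whose rise from the floor was larger still. It was not left out for its control values, though these may be failed estimates. C3943_15875, at positions 3324084 to 3324851, went from 1.65 ± 0.814 to 1647 ± 1408 FPKM (SD, n = 2; log2 fold change 8.99 ± 0.66 SE, limma adjusted p = 0.00127), with 8.30 within replicate 1 and 9.68 within replicate 2. C3943_12345 rose by 8.02 ± 0.65 SE (7.35, 8.69) and C3943_12335 by 7.49 ± 0.58 SE (6.52, 8.46) on the log2 scale; reads shared between such copies could not be separated here. The gene C3943_15310 of the iron-sulfur protein HesB, between arsA and arsM, rose by 7.36 ± 0.55 SE (7.23, 7.49), but it shares its locus with arsA in the authors' deposited table, where its q-value was 0.454. C3943_15285, an ArsR repressor gene at the start of the operon, rose by 7.17 ± 0.35 SE (7.65, 6.69), and shares its locus with arsB C3943_15290 there. The sulfur transfer gene dsrE, C3943_24875, went from 21.3 ± 0.151 to 3627 ± 1784 FPKM (SD, n = 2). The ATPase gene C3943_16025 rose by 7.18 (6.25, 8.12), with 15029 FPKM of SD around a mean of 16229 in the exposed cells, and the oxidoreductase gene C3943_15055 rose by 7.11 (7.99, 6.23).

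The largest fall was that of a gene with very high FPKM in the controls. C3943_16755, annotated as a transcriptional regulator at positions 3512149 to 3512319, went from 58001 ± 722 to 807 ± 94.2 FPKM (SD, n = 2; log2 fold change -6.17 ± 0.30 SE, limma adjusted p = 0.000469), with -6.06 within replicate 1 and -6.28 within replicate 2. The small YhfH family gene C3943_22480 fell from 70027 ± 6384 to 4258 ± 3229 FPKM (SD, n = 2). Both loci are shorter than the length offsets of 202 and 204 bp fitted here in control 2 and arsenopyrite 2. FPKM of such short loci are uncertain as levels of a transcript. A neighbouring group fell together: the 2-nitropropane dioxygenase gene C3943_00255, the thioesterase gene C3943_00250 and the carbonic anhydrase gene C3943_00260, with log2 fold changes of -4.71 (-4.73, -4.69), -4.35 (-4.38, -4.31) and -3.48 (-3.22, -3.75). Nearby, paaJ, a subunit gene of the phenylacetyl-CoA oxygenase, fell from 44.2 ± 1.34 to 2.27 ± 0.62 FPKM (SD, n = 2). Log2 fold changes of -3.88 (-3.62, -4.14) for the predicted sulfate exporter gene C3943_26460, -3.86 (-4.35, -3.37) for the acetyl-CoA acyltransferase gene C3943_03355, -3.60 (-3.50, -3.70) for the LytTR regulator gene C3943_00725 and -3.59 (-3.62, -3.55) for the acetate symporter gene C3943_05635 completed the 10 largest falls. With no filter on low values, C3943_22480 and C3943_03355 had limma adjusted p of 0.0557 each.

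In the authors' deposited table, 1549 genes had a q-value under 0.05, 882 higher and 667 lower with arsenopyrite. The authors' deposited table of changed genes held 1661 genes, which are those with p under 0.05 and an absolute log2 ratio of at least 1, and 167 of them had a q-value of 0.05 or more. Of the genes tested with limma, 1547 had a q-value under 0.05 in the authors' deposited table, and 937 of these were among the 1081 limma calls, all in the same direction.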

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

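The settings on loci of 1 gene, on such loci of at least 450 bp and on genes above the floor were chosen after the data were examined. The count of 1081 genes was 479 with no filter on low values, and 427 to 1940 when a library was left out (474 and 427 without control 1 and 2, 1940 and 1531 without arsenopyrite 1 and 2, the lone library being taken to vary like the other group). The count of 1749 genes with a 2-fold difference and separate groups was 907 on single-gene loci of at least 450 bp, where 2852 genes were left to test. The 8 lists past camera became 5 with no filter and 0 with an estimated correlation, which is poorly known from 4 libraries. The 907 were drawn from fewer genes; for the other moves the cause was not tested. In the remaining settings, apart from the replicate block below, these 3 counts stayed within 1.5 times. Quantile normalization moved the median log2 fold change of all genes from 0.07 to -0.13, and the 1081 calls became 392 higher and 516 lower. Of the 46 named genes past the threshold, 36 stayed past it under every setting, 7 lost it when a library was left out and 3 with no filter, and none changed direction. Of the 8 lists, arsenic resistance, phosphate uptake, sporulation and fatty acid degradation passed under every setting other than the estimated correlation. A count test planned in case of counts was not run, since the values are FPKM.

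With the replicate number as a block limma called 1731 genes, 966 higher and 765 lower. In camera the block gave an adjusted p of 0.0655 for the motility list, 0.0507 for the nitrogen list and 0.0304 for ribosomal and transfer RNA, and put no other list on another side of the threshold. Across genes, the deviations of same-numbered libraries from their group means had a Pearson r of 0.181 and a Spearman correlation of 0.296. Same-numbered libraries are also alike in whether their low values came out as whole reads. With 2 pairs and no label of a shared batch, the numbers were not taken to pair the cultures. Depth limits the low genes most: at 1000 bp, 1 FPKM in control 2 stands for few reads, since 1 read is worth 0.158 FPKM.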

Other observations

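The regions, runs and patterns described here were chosen after the values were seen. Regions in which every gene was called start and end where a run of called genes does. Their full counts follow from how they were drawn. Of the tests below, that on background reads was set before its values were seen; those on scaling, on the making of the values, on sequencing depth, on zinc and on shared reads were set after related values had been seen. A pair of values in brackets gives a median or log2 fold change within replicate 1 and within replicate 2. Called genes lay side by side: in locus tag order there were 26 runs of at least 5 neighbours called in the same direction, 17 higher and 9 lower, which held 195 genes, while no more than 2 runs arose in any of 1000 shuffles of the calls. Genes of an operon share a transcript, so the runs are not independent changes. A long group of falls was the phenylacetate degradation region from C3943_00160 to C3943_00260, where 20 of 21 tested genes fell, with a median log2 fold change of -2.28 (-2.37, -2.12). It holds paaG, paaH, paaI and paaJ, which attack the aromatic ring, and livF of branched-chain amino acid uptake. A region of a bacterial microcompartment, C3943_19240 to C3943_19275, fell in 8 of 8 genes, with a median of -2.46 (-2.09, -2.999), among them the propanediol utilization gene C3943_19255. The region with acetoin and acetate utilization genes from C3943_09955 to C3943_09975 fell in 5 of 5 genes, with a median of -2.20 (-2.30, -2.57). Among them were ccpA, the regulator of carbon catabolite control, at -1.32 (-1.33, -1.31) and the acetate CoA ligase gene C3943_09975 at -3.29 (-3.60, -2.98). In a region with acyl-CoA genes from C3943_02840 to C3943_02860, 5 of 5 genes fell, 1 of them hypothetical, with a median of -2.06 (-1.87, -2.19). In another from C3943_03350 to C3943_03380, 7 of 7 fell, 1 of them hypothetical, with a median of -2.46 (-2.75, -2.18).

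Among the rises, a sulfur transfer cluster from C3943_24845 to C3943_24895 had 11 of 11 genes higher, with a median log2 fold change of 5.69, 6.24 within replicate 1 and 5.31 within replicate 2. Beside dsrE and 2 rhodanese genes it holds the hypothetical gene C3943_24870, which rose by 8.18 (8.42, 7.93). The arsenic region was wider than the annotated ars genes: all 11 genes from C3943_15275, a monooxygenase gene, to C3943_15325, a flavoprotein gene, were higher, with a median of 6.18 (6.49, 5.90). In the copper region, C3943_00280 of the copper-sensing repressor CsoR rose by 4.92 (5.39, 4.45). The nickel and metallophore transport region from C3943_14835 to C3943_14860 had 6 of 6 genes higher, with a median of 2.78 (2.87, 2.68), and the manganese transport region from C3943_14940 to C3943_14955 3 of 4, with a median of 2.72 (1.81, 3.63). In a region with members of the list of transposases, integrases and prophage genes, C3943_17840 to C3943_17960, 23 of 25 genes were higher, with a median of 3.60 (3.03, 4.24). Its runs of 7 and 16 genes held 1 and 2 list members and 4 and 12 hypothetical genes. In another from C3943_10765 to C3943_11010, where 6 genes were listed at 0 in both controls, 33 of 50 were higher, with a median of 2.52 (1.91, 3.02). Of its runs, C3943_10765 to C3943_10820 held 0 list members and 7 hypothetical among 12 genes. The run C3943_10945 to C3943_10980 held 2 and 4 among 8. A run of 7 genes with hypothetical products, C3943_08125 to C3943_08155, had a median of 4.24 (3.64, 4.57). Beside the thioredoxin gene C3943_15050, listed at 0 in both controls and at 86.9 and 42.3 FPKM in arsenopyrite 1 and 2, the oxidoreductase gene C3943_15045 rose by 6.68 (6.70, 6.66).

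The exposed libraries differed from each other in several gene lists. Between arsenopyrite 2 and 1, the median log2 difference was 1.12 for sporulation, 1.07 for ribosomal proteins, 1.04 for branched-chain and aromatic amino acid synthesis, 0.92 for phosphate uptake, 0.80 for the respiratory chain and 0.70 for the prophage list, but -0.56 for arsenic resistance. The gap of 1.683 between the sporulation and arsenic lists, against a summed spread of 0.716, restates the pattern from which these lists were picked. It shows only that a scaling difference between the libraries, which moves all genes alike, does not by itself give both values. A different making of replicate 1 and 2 values, which the share of whole reads leaves open, could also part the controls. There the same gap was 0.077, against a summed spread of 0.698. Most arsenic resistance genes were low in the controls. A difference that depends on level need not show there, so the control gap does not decide. No biological explanation was tested.

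Of the 72 tested members of the list of transposases, integrases and prophage genes, 43 had a control mean under 5 FPKM, and several of these rose. Background reads that raise every nearly silent gene could account for part of this: 668 genes of no list with a control mean under 5 FPKM, outside the runs with prophage genes, had a median log2 fold change of 0.923, against 1.503 for these 43, so that it passed the bound set beforehand, 0.5 of the median of the 43, or 0.752. Selecting on low controls favours rises in both sets. The regions above with members of the list lay higher, at 3.60 and 2.52, but were picked because their genes rose. The median of the 43 still lay above the range of 0.587 to 1.29 of random draws of 43 from the other set. Against 10000 random lists matched on mean expression the whole list lay at percentile 99.9. But the other set left out the called runs that held members of the list, while the 43 kept any members of them. It did not leave out the run of 12 risen genes from C3943_10765 to C3943_10820, which held 0 members but lies in a region with members above. Such genes raise the median of the other set, which favours background reads. Both checks also take genes as independent though neighbours share transcripts, so they do not weigh against background reads. Deeper sequencing stays open. Over 41 list members on single-gene loci of 450 to 3000 bp in replicate 2, the median ratio of recovered reads was 2.033. Totals on the loci used for depth differed by 1.34, so the ratio was short of the factor set for excluding it. By the worth of 1 read, 0.158 and 0.0911 FPKM at 1000 bp, the totals behind the FPKM differed by more. Unlike the 43, the 41 were not picked for low controls. On single-gene loci of at least 450 bp the list's median log2 fold change was only 0.279, so the test could not decide.

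The L33 gene rpmG C3943_25000 rose by 4.36 (4.79, 3.93) on the log2 scale next to C3943_24995, a gene of the CobW family of metal chaperones, which rose by 3.43 (3.42, 3.45), while rpmG C3943_12875 fell, at -1.33 (-1.63, -1.03), and rpmG C3943_26230 stood at 0.10 (0.726, -0.523). Reads shared between the copies stay open, since the gap of 5.69 between the rising and the falling copy restates the pattern and decides nothing. Copies of L33 without a zinc site are known from zinc-starved Bacillus, so a response to zinc shortage is a candidate explanation. Over the 5 tested zinc transport and repeated ribosomal protein genes, 1 was called higher and the median log2 fold change was 0.7131, which met the written bound against it but not by more than its spread of 0.611. That spread condition was added after the values were seen. The 3 L33 genes are themselves among the 5, and the 1 called higher is the rising L33 gene, so the test leaves zinc open.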
